A study of Mus musculus with 2 samples.

How the data were processed

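Total RNA of sorted epithelial cells and of sensory ganglia was profiled by SCRB-seq, in which each sample carries a barcode and a pool of samples is sequenced together. The 2 pools, of the Cck and the Pyy reporter line, were deposited as a table of whole-number counts per gene and barcoded library, made with STAR and featureCounts on mm10, per the submitters' processing notes. The deposited size factors are ratios of library depth made with DESeq2, per the submitters' processing notes, and factors recomputed here from the counts differed from them by at most 5e-10. No version of STAR, featureCounts or DESeq2 is given in the sources used here. How molecular identifiers were collapsed, whether reads with several matches were counted, and whether strand was used are not given there either.

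The Cck table holds 37702 genes in 15 libraries of 5 animals and the Pyy table holds 46569 genes in 26 libraries of 12 animals, with 37101 genes in both. Of their symbols, 37144 and 45777 were found in GENCODE M21 (GRCm38/mm10), which gave the positions. Populations and animals of the 41 libraries came from the deposited sample information and column names, never from the values. Columns are marked GFP or NEG, and NEG was read here as the samples marked minus in the barcode lists, taken to be the other epithelial cells named in the series design. The barcode lists name 2 technical replicates per sample. The sample information names replicate 2 for the unlabelled small intestinal library of Cck mouse 3 and the dorsal root libraries of Pyy mice 4 and 10, and replicate 1 for the rest. Whether a column holds that replicate alone, and why it was taken, is not given in the sources used here. The dorsal root sample of Pyy mouse 1 is named in the barcode lists of both pools but has a column only in the Pyy table, for which no reason is given. Each animal gave 1 library per population, so the animal is the replicate. The sex recorded for the Pyy animals matched sex-linked transcripts in 26 of 26 libraries. Mice are numbered in ascending order of the deposited animal number within each line.

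Counts were tested with edgeR's quasi-likelihood test (R 4.3.3, edgeR 4.0.16, limma 3.58.1) after TMM scaling and edgeR's low-count filter by population, with Benjamini-Hochberg adjustment at a false discovery rate of 0.05. All log2 fold changes are fitted values from that test. Each SE was taken as the absolute log2 fold change divided by the square root of the test's F statistic. It is therefore not an error that the model itself estimated. There were 6 comparisons. Labelled and unlabelled epithelium were compared within each segment on those libraries alone. Neurons were compared with the mean of both epithelial populations of their table. The label effects of the segments were compared as an interaction over the 4 epithelial populations, so that a constant table effect on a gene cancels. TMM scaling placed fold changes -0.40 (small intestine) and -0.88 (colon) from those of unscaled CPM, which is on the log2 scale.

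The 23 gene lists were fixed before the data were examined: enteroendocrine hormones, enteroendocrine identity and secretory machinery, nutrient and metabolite sensing, toll-like receptors, other pattern recognition, synaptic and vesicle release, ion channels, enterocyte, colonocyte, goblet, Paneth, tuft, stem and cycling, immune, stromal and endothelial, glia, blood, pan-neuronal, nodose neuron, dorsal root neuron, gut signal receptors, gut region, and immediate early and dissociation stress. Each was tested with limma's camera on edgeR log CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Levels are CPM of the library total. Single values were compared by two-sided exact permutation tests (Python 3.11.15, scipy 1.17.1, numpy 2.4.6, pandas 2.3.3). Except for a sign-flip test on same-animal pairs, these ignored the pairing of libraries by animal, as did the main edgeR fits.

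Named genes followed a rule fixed before the data were examined. It takes Cck, Pyy, Gcg and every toll-like receptor, then the largest fold changes on each side among called genes whose libraries separate the populations and whose mean is at least 10 CPM in the higher one, and up to 4 members per list with the smallest p. Predicted models and pseudogenes were passed over in the part on large fold changes, except in the comparison of segments. Genes named in a segment were also looked up in the comparison of segments, and the text names part of what the rule gives. Some genes that the rule gives are not reported here. Tph1 in both segments and in the comparison of segments, Tac1 in the colon and in the comparison of segments, Nmb in the colon, Lmx1a and Pou2f3 in the comparison of segments, and Tlr5 in the comparison of segments fall outside the rule and were chosen after their values were seen.

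A gene was treated as having a near-identical copy where at least 0.1 of the 46-base words in the last 500 bases of its transcripts occur in another gene; 55187 genes were scored. That share was lowered after the data were seen. The tables appear to treat such copies differently, since several mitochondrial and globin transcripts are near 0 counts in the Cck table alone.

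The fit was tested on simulated counts with 200 changed genes per comparison, drawn from each comparison's own means and library sizes. It recovered 22% of 2-fold and 65% of 4-fold changes in the small intestine, 50% and 93% in the colon, 21% and 70% for nodose against epithelium, 82% and 97% for dorsal root against epithelium, 14% and 53% for the comparison of segments, and 38% and 95% between ganglia. The false calls were 1.14%, 5.92%, 7.14%, 4.79%, 0% and 3.62% of those made. The changed genes were taken only from those with higher mean counts and moved in random directions. Every other gene was given the same mean in all populations. These rates therefore do not cover genes with low counts, such as most toll-like receptors. Nor do they cover shifts in composition as large as those of the real data. A count of 3 was taken as the floor, which covers counting error only.

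Labelled and unlabelled libraries of the same animal are paired by the animal. Deviations from the population means correlated at 0.0365 to 0.0813 (median 0.0645) in the 5 same-animal pairs of the small intestine, against a median of -0.0179 between animals. In the 5 pairs of the colon they correlated at 0.0657 to 0.182 (median 0.131), against -0.0184.

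Alternatives fixed before the data were examined were DESeq2 size factors, the DESeq2 Wald test (DESeq2 1.42.0), no low-count filter and leaving out each library. Where ganglia were compared, only neuron libraries were left out. The other alternatives fixed then were run only between labelled and unlabelled cells. They were a filter of at least 10 counts in every library of either population and all populations in 1 fit. They also included the animal as a block, thinning to the lowest total and glmTreat against a 2-fold change. Others, chosen after the data were seen, are named in the closing part on processing. Keeping libraries of low depth and treating barcoded libraries as separate replicates were not run, since every library was above the depth at which it would have been left out and each animal had 1 library per population.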

Results

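Gene expression was measured in sorted gut epithelial cells and sensory ganglia of mice carrying a green fluorescent reporter for either of 2 gut hormone genes. In the Cck line, whose reporter marks cells making cholecystokinin, 5 animals each gave labelled epithelial cells of the proximal small intestine, the unlabelled epithelial cells of the same segment, and nodose ganglion neurons, the vagal sensory neurons that innervate viscera. In the Pyy line, whose reporter marks cells making peptide YY, 12 animals gave dorsal root ganglion neurons (n = 12), the spinal sensory neurons, and some of them also labelled (n = 6) and unlabelled (n = 8) colonic epithelium. Animals are numbered here as Cck mice 1 to 5 and Pyy mice 1 to 12, in ascending order of the deposited animal number. Each population of an animal was a separate barcoded SCRB-seq library, an RNA-sequencing format for small inputs that reads the 3′ ends of transcripts. Total counts ran from 5273085 to 20585745 in labelled and from 4515170 to 14413619 in unlabelled small intestinal libraries. Nodose libraries held 4011371 to 16483601 counts. Colonic libraries held 6598025 to 13924429 counts when labelled and 12206725 to 41718040 when unlabelled. Colonic totals were lower when labelled (two-sided exact permutation p = 0.00266, 0.00799 adjusted over 6 library measures). Small intestinal totals were not shown to differ (exact permutation p = 0.1825, adjusted 0.219). Dorsal root libraries held 1778087 to 19666714 counts. A count of 3 corresponded to 0.0719 CPM (gene counts scaled by the library total) in the deepest library and 1.69 CPM in the shallowest, which covers counting error only.

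Cck-labelled cells of the small intestine were compared with the other epithelial cells around them to find which transcripts mark them. Cck itself (chromosome 9, 121489824 to 121495694, minus strand, GRCm38/mm10) stood at 6522 ± 4001 CPM (SD, n = 5) in labelled and 97.2 ± 50.5 CPM (SD, n = 5) in unlabelled libraries. The log2 fold change was 5.67 (SE 0.45, edgeR adjusted p = 5.19e-07). The labelled cells held many other hormone transcripts besides. Sct (secretin) stood at 50530 ± 8934 against 685.5 ± 303.8 CPM (SD, n = 5 each). Pyy stood at 5458 ± 922 against 73.9 ± 42.6 CPM and Gcg (proglucagon) at 2208 ± 1447 against 34.2 ± 14.3 CPM. Unlabelled levels of these hormones may partly be transcripts exchanged within the sequencing pool, a candidate set out in the closing part. Nodose libraries of the same pool held hormones at a median of 2.38% of the pool level, so such a background may partly set the hormone folds. Ghrl (ghrelin) was higher by 5.57 (SE 0.24) on the log2 scale, and Tph1 and Tac1, which mark the serotonin-making enterochromaffin cells, by 6.02 (SE 0.32) and 4.96 (SE 0.26), Tph1 being named after its values were seen. Across 13441 genes tested, 2078 were higher and 2024 lower in labelled libraries at a false discovery rate of 0.05.

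Groups that rose in labelled small intestinal cells included those of secretion and of excitable cells. Of the hormone list, 12 of 14 measured members rose (camera adjusted p = 5.03e-12; adjusted p = 0.0854 with an estimated correlation). All 26 measured members of the enteroendocrine identity and secretory list rose (camera adjusted p = 2.97e-23; adjusted p = 0.0854 with an estimated correlation). They included Neurod1, a transcription factor of endocrine cells (5.95, SE 0.30), and the granins Chga (6.12, SE 0.33) and Chgb (6.35, SE 0.40). Of the nutrient and metabolite sensing list, 12 of 14 rose and 1 fell (camera adjusted p = 6.28e-08; adjusted p = 0.0107 with an estimated correlation). Members included the long-chain fatty acid receptor Ffar1 (6.65, SE 0.47), the short-chain fatty acid receptor Ffar2 (5.27, SE 0.38) and the irritant-gated channel Trpa1 (5.23, SE 0.30). Vesicle release genes rose in 19 of 32 and fell in 3, with Stxbp5l at 6.42 (SE 0.47), Syt13 at 5.19 (SE 0.32) and the fusion protein gene Snap25 at 2.37 (SE 0.41); without the unlabelled library of Cck mouse 4, Stxbp5l stood at 7.28 and Snap25 at 3.08. That list had a camera adjusted p of 8.62e-08, with adjusted p = 0.261 with an estimated correlation. Ion channel genes of excitable cells rose in 13 of 19 (camera adjusted p = 1.18e-07; adjusted p = 0.144 with an estimated correlation). Members included the voltage-gated sodium channel Scn3a (6.32, SE 0.36).

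Receptors for gut signals that the list was fixed to describe on neurons rose in 6 of 11 measured members, including the incretin receptor Glp1r (4.49, SE 0.50) and the somatostatin receptor Sstr1 (4.86, SE 0.53; 5.89 without the unlabelled library of Cck mouse 2). That list's camera adjusted p was 0.0255, but 0.0554 with the animal as a block, and its adjusted p was 0.296 with an estimated correlation. Tuft cell markers also rose, in 9 of 10 members (camera adjusted p = 6.18e-06; adjusted p = 0.0958 with an estimated correlation). Members included Sh2d6 at 4.43 (SE 0.43). Immediate early and dissociation stress genes rose in 12 of 18 (camera adjusted p = 2.72e-05; adjusted p = 0.149 with an estimated correlation). Members included Junb at 1.46 (SE 0.14) and Egr1 at 1.79 (SE 0.23). Outside the lists, the largest increases among separated genes were in the vasopressin receptor Avpr1b (6.91, SE 0.81), the monooxygenases Cyp2f2 (6.85, SE 0.63) and Fmo2 (6.43, SE 0.39), Apom (apolipoprotein M; 6.60, SE 0.63) and Gast (gastrin; 6.32, SE 0.83). Without the unlabelled library of Cck mouse 4, Avpr1b, Apom and Gast stood at 7.60, 7.23 and 7.10. Without that of mouse 3 Avpr1b stood at 7.61, and without that of mouse 1 Cyp2f2 stood at 7.55. Thinned to the lowest total, Avpr1b stood at 6.26.

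Markers of the absorptive, goblet and Paneth lineages were lower in labelled small intestinal cells. Enterocyte genes fell in 17 of 21 members (camera adjusted p = 1.37e-10; adjusted p = 0.108 with an estimated correlation). Members included the brush border phosphatase Alpi at -2.56 (SE 0.25) and the triglyceride-synthesis gene Dgat1 at -2.23 (SE 0.17). Goblet genes fell in 12 of 14 (camera adjusted p = 1.83e-08; adjusted p = 0.0185 with an estimated correlation). Muc2, the gel-forming mucin, stood at 106.0 ± 18.3 against 1355 ± 144 CPM (SD, n = 5 each), and Zg16 and Clca1 at -3.80 (SE 0.18) and -3.83 (SE 0.19). All 10 Paneth genes fell (camera adjusted p = 1.40e-09; adjusted p = 0.144 with an estimated correlation). Members included Pla2g2a (-3.50, SE 0.32) and the defensin-processing protease Mmp7 (-3.19, SE 0.26). Alpha-defensin genes took 0.625 ± 0.186% of counts in labelled and 5.56 ± 3.35% in unlabelled libraries (SD, n = 5 each; two-sided exact permutation p = 0.00794, 0.0119 adjusted over 6 library measures). That permutation test ignored the pairing of libraries by animal. Stem and cycling genes fell in 9 of 15 (camera adjusted p = 0.000337; adjusted p = 0.19 with an estimated correlation). Members included Birc5 at -1.42 (SE 0.19) and Cdk1 at -1.41 (SE 0.19). Colonocyte genes rose in 3 and fell in 7 of 15 (camera adjusted p = 0.002; adjusted p = 0.0968 with an estimated correlation). Members included Guca2a, the guanylin gene, at -3.02 (SE 0.17). Immune genes rose in 1 and fell in 6 of 16 (camera adjusted p = 0.0255; adjusted p = 0.431 with an estimated correlation). Cd74 fell by 1.94 (SE 0.21) on the log2 scale and the complement gene C1qa rose by 4.66 (SE 0.53). Other large decreases were in Fer1l6 (-4.54, SE 0.67; -5.48 without the labelled library of Cck mouse 1), Slc10a5 (-4.32, SE 0.71), the tryptophan-degrading enzyme Ido1 (-4.15, SE 0.41), Mptx2 (-3.69, SE 0.45) and Lrrc26 (-3.67, SE 0.59).

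The remaining lists did not pass the camera test in the small intestine. The other pattern recognition list had 1 higher and 4 lower of 25 (adjusted p = 0.263), the lower ones including the inflammasome genes Nlrp6 (-2.13, SE 0.23) and Nlrc4 (-2.12, SE 0.45). Stromal genes had 1 higher, Vim (3.24, SE 0.50; 3.83 without the unlabelled library of Cck mouse 4), and 1 lower of 6 (camera adjusted p = 0.834). Glial genes had 3 lower of 8 (0.227), pan-neuronal genes 1 higher and 3 lower of 18 (0.76), and blood genes, with 3 measured, had an adjusted p of 0.584. Nodose neuron genes had 2 higher of 6 (adjusted p = 0.834; median -0.98, mean 0.86), dorsal root neuron genes 3 higher and 1 lower of 12 (0.834; median -0.67, mean 0.09), and gut region genes 1 higher of 10 (0.958). Adjusted over the list alone, the counts above changed to 1 higher and 1 lower of the 2 toll-like receptors tested, 3 lower and no higher pattern recognition genes, 20 higher vesicle genes and 16 higher ion channel genes. On the same basis there were 19 lower enterocyte genes, 10 lower colonocyte genes, 9 lower immune genes, 2 higher and 2 lower stromal genes, 4 lower glial genes and 3 lower dorsal root genes. The pan-neuronal and gut region lists lost their 3 lower and 1 higher calls respectively. The neuronal gene Stmn2 (-1.52, adjusted p = 0.0485), the glial gene S100b (-2.32, adjusted p = 0.0249) and the region gene Pdx1 (0.95, adjusted p = 0.0303) lost their calls with the animal as a block. They then stood at -0.82 (adjusted p = 0.195), -1.20 (0.147) and 0.93 (0.069). Without the unlabelled library of Cck mouse 4, Stmn2 stood at -0.35 (adjusted p = 0.345) and S100b at -0.59 (adjusted p = 0.251).

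**Figure D1:**
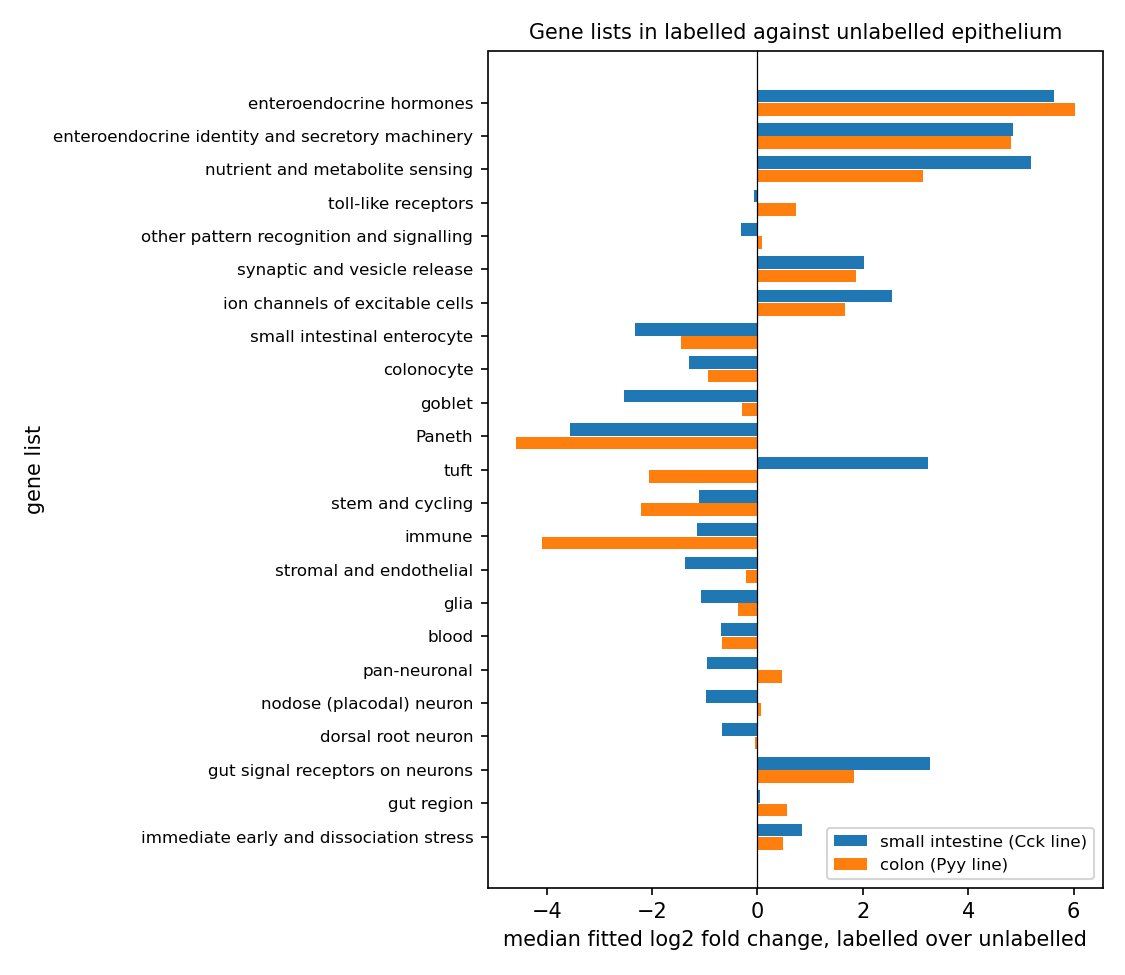
Median fitted log2 fold change (x axis) of the measured members of each of the 23 gene lists (y axis), labelled over unlabelled epithelium; blue bars are the small intestine of the Cck line and orange bars the colon of the Pyy line. The enteroendocrine hormone bars reach 5.62 and 6.02, the Paneth bars -3.56 and -4.58, and the tuft bars point in opposite directions, 3.24 and -2.06.

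Pyy-labelled colonic cells were compared with the other colonic epithelial cells in the same way. Pyy (chromosome 11, 102106676 to 102107832, minus strand, GRCm38/mm10) stood at 74200 ± 24560 CPM (SD, n = 6) in labelled and 345.4 ± 578.0 CPM (SD, n = 8) in unlabelled libraries. The log2 fold change was 6.89 (SE 0.75, edgeR adjusted p = 1.87e-06). Gcg followed at 6.95 (SE 0.59), Insl5, a relaxin-family peptide of colonic L cells, at 6.92 (SE 0.88; 7.71 with the animal as a block), Cck at 6.70 (SE 0.51) and Sst (somatostatin) at 6.02 (SE 0.55). The unlabelled library of Pyy mouse 2 held the highest Pyy, Gcg, Cck and Insl5 of its group, and without it the folds were 8.11, 7.76, 7.43 and 8.55. In the DESeq2 Wald test Cck stood at 4.23 (adjusted p = 0.000182). Unlabelled hormone levels may partly be transcripts exchanged within the pool here too. Of 16039 genes tested, 3806 were higher and 4078 lower in labelled libraries.

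Endocrine groups rose in the colon as well. In the hormone list 12 of 15 members rose and 3 fell (camera adjusted p = 1.25e-06; adjusted p = 0.328 with an estimated correlation). The 3 that fell, all named after their values were seen, were Tph1 (-1.75, SE 0.47), Tac1 (edgeR adjusted p = 0.003) and Nmb (-0.82, SE 0.32), and the Nmb call was lost in 17 of 25 alternatives. TMM scaling placed the median fold change -0.88 from that of unscaled CPM in the colon and -0.40 in the small intestine, so the Nmb difference is no larger than that shift and the Tac1 difference is little larger. All 25 identity and secretory genes rose, including the transcription factors Pax6 (5.39, SE 0.22) and Insm1 (4.30, SE 0.25) (camera adjusted p = 4.12e-20; adjusted p = 0.0865 with an estimated correlation). Nutrient and metabolite sensing genes rose in 13 of 15 (camera adjusted p = 5.42e-08; adjusted p = 0.0617 with an estimated correlation). Members included the lipid receptor Gpr119 at 6.74 (SE 0.39), the bile acid receptor Gpbar1 at 6.65 (SE 0.41) and the sulfonylurea receptor Abcc8 at 5.17 (SE 0.19). Vesicle release genes rose in 22 and fell in 1 of 31 (camera adjusted p = 3.88e-08; adjusted p = 0.183 with an estimated correlation). Members included Cplx2 at 5.05 (SE 0.30) and Syt13 at 5.37 (SE 0.43). Ion channel genes rose in 15 of 22 (camera adjusted p = 1.47e-06; adjusted p = 0.256 with an estimated correlation). Members included the calcium channel Cacna1a at 3.48 (SE 0.22) and Scn3a at 4.73 (SE 0.38). Gut region genes rose in 8 of 16 (camera adjusted p = 0.0246; adjusted p = 0.287 with an estimated correlation). Members included the homeobox genes Hoxb8 (2.88, SE 0.26) and Hoxb9 (2.49, SE 0.23). Pan-neuronal genes rose in 8 and fell in 1 of 17, with Map2 at 4.88 (SE 0.44); their camera adjusted p of 0.0246 became 0.116 with the animal as a block, and the adjusted p was 0.758 with an estimated correlation. Avpr1b (6.81, SE 0.52), Mrln (6.72, SE 0.42) and the antisense transcript Cyp4x1os (7.05, SE 0.42) were other large increases, with Avpr1b at 7.68 and Mrln at 7.40 without the unlabelled library of Pyy mouse 2.

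Paneth, immune and proliferating-cell transcripts were lower in labelled colonic cells. Alpha-defensin genes took 4.11 ± 2.54% (SD, n = 6) of counts in labelled and 32.2 ± 22.6% (SD, n = 8; range 6.47 to 73.2%) in unlabelled libraries (two-sided exact permutation p = 0.00133, 0.00799 adjusted over 6 library measures). Of the Paneth list 9 of 10 members fell (camera adjusted p = 0.000696; adjusted p = 0.578 with an estimated correlation). Itln1 stood at 359.7 ± 212.4 against 2562 ± 1713 CPM and Lyz1 (lysozyme) at 482.0 ± 248.1 against 3801 ± 2890 CPM, with Mmp7 at -4.35 (SE 0.74). Defa24 (-4.64, SE 0.96) and Defa30 (-4.64, SE 0.96) share 3′ sequence with other defensin genes, as Lyz1 does with Lyz2 (-4.72, SE 0.98), so their separate values are uncertain. Without the unlabelled libraries of Pyy mice 3 and 5, which held the largest defensin shares, Itln1, Lyz1, Lyz2, Defa24, Defa30 and Mmp7 stood at -2.69, -2.84, -2.84, -2.85, -2.85 and -3.07, with edgeR adjusted p values of at most 0.000995. Without that of Pyy mouse 3 alone they stood at -3.43, -3.53, -3.55, -3.62, -3.64 and -3.56. All 16 measured immune genes fell (camera adjusted p = 0.000397; adjusted p = 0.578 with an estimated correlation). Members included Ptprc, the pan-leukocyte gene (-2.97, SE 0.63), and the antigen presentation gene H2-Aa (-1.42, SE 0.23). Ptprc ran from -3.67 to -2.60 over the alternatives. Rac2 (-3.87, SE 0.73; -4.62 with the animal as a block), a GTPase of blood cells, and the chemokine Ccl9 (-3.45, SE 0.35) were also lower. Stem and cycling genes fell in 14 of 16 (camera adjusted p = 9.17e-08; adjusted p = 0.183 with an estimated correlation). Members included Smoc2 at -2.38 (SE 0.21) and the replication gene Mcm5 at -2.35 (SE 0.22). Colonocyte genes rose in 1 and fell in 8 of 20 (camera adjusted p = 0.0235; adjusted p = 0.753 with an estimated correlation). Members included Guca2a at -1.88 (SE 0.33) and the keratin Krt19 at -1.75 (SE 0.31).

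Tuft markers, which rose in the small intestine, had 8 lower and 1 higher of 10 members in the colon: Dclk1 stood at -1.80 (SE 0.35), and Hpgds, a prostaglandin D synthase, at 3.02 (SE 0.27). The tuft list did not pass without the animal block (camera adjusted p = 0.0834) and passed with it (0.0133), and immediate early genes, with 4 of 18 higher including Junb (1.40, SE 0.24), went from 0.243 to 0.00489. With an estimated correlation and no block, their adjusted p values were 0.706 and 0.758. Other lists did not pass. Goblet genes had 1 higher, Bcas1 (1.41, SE 0.19), and 5 lower, Spink4 among them (-2.17, SE 0.46), of 14 (camera adjusted p = 0.12). Enterocyte genes had 2 higher, the peptide transporter Slc15a1 among them (2.41, SE 0.37), and 11 lower, Mttp among them (-1.78, SE 0.33), of 21 (0.174). Gut signal receptors had 6 higher, Sstr3 among them (4.13, SE 0.54; 5.01 without the unlabelled libraries of Pyy mice 3 and 5), and 1 lower of 11 (0.0986). Pattern recognition genes had 6 higher and 6 lower of 24 (0.992), with a median of 0.08 and a mean of -0.00. Within the last list Nlrp6 (-1.56, SE 0.19), the peptidoglycan-binding Pglyrp1 (-1.84, SE 0.21) and Tirap (-1.38, SE 0.25) were lower and Ifih1, an RNA sensor, was higher (0.92, SE 0.17). Stromal genes had 1 higher of 7, Vim (4.91, SE 0.36) (adjusted p = 0.466; median -0.22, mean 0.73). Glial genes had 2 higher and 1 lower of 9 (0.887; median -0.37, mean 0.15) and nodose neuron genes 2 higher of 6 (0.466). In the colon, dorsal root neuron genes had 5 higher and 2 lower of 15 (0.648; median -0.05, mean 0.47), and blood genes, with 4 measured, an adjusted p of 0.716. Adjusted over the list alone, colonic counts differed from those above only for pattern recognition (7 higher), vesicle release (23 higher), stem and cycling (15 lower), dorsal root (3 lower), immediate early genes (1 higher) and the toll-like receptors, where the 1 lower call was lost.

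**Figure D2:**
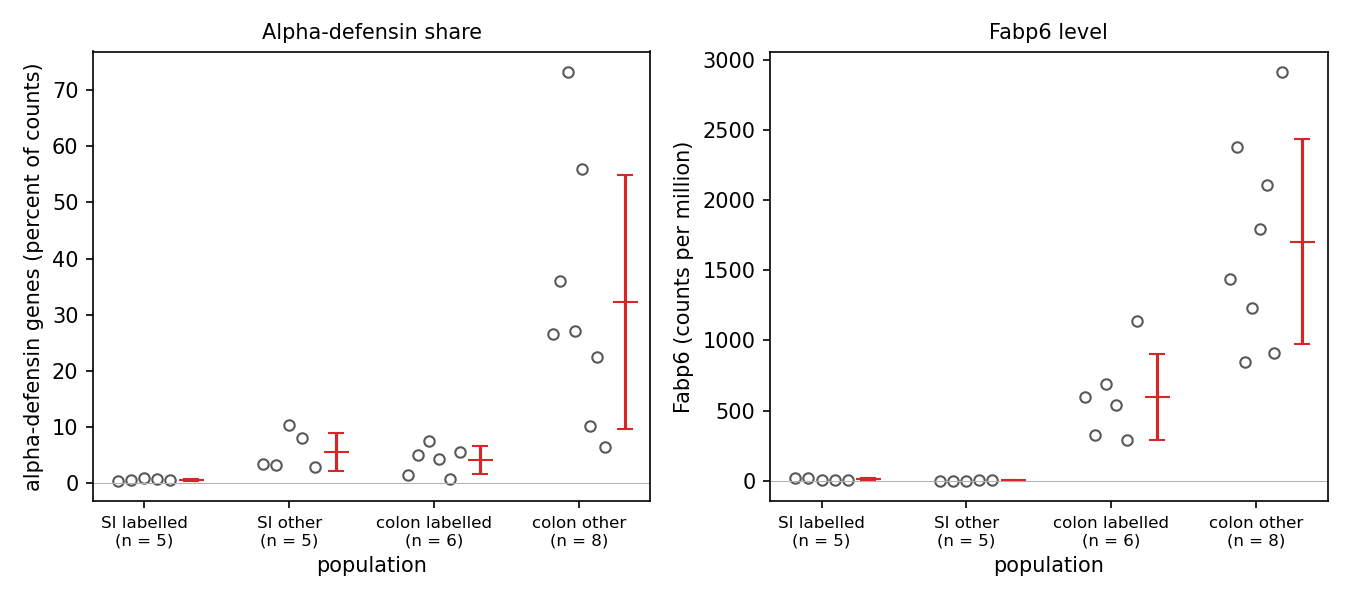
Left, share of all counts (percent, y axis) taken by alpha-defensin genes; right, Fabp6 (CPM, y axis); each circle is a library, grouped by epithelial population (x axis; SI, small intestine; other, unlabelled), and red marks give the mean and SD. Unlabelled colonic libraries span 6.47 to 73.2% defensin counts and 848.2 to 2915 CPM of Fabp6, while small intestinal libraries hold at most 21.4 CPM of Fabp6. Many defensin genes have near-identical copies, which the tables of the 2 segments appear to treat differently. Defensin shares are therefore not comparable between segments.

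Toll-like receptors recognise microbial molecules, and every member was examined because the study's title names a microbial pattern. Tlr5, the flagellin receptor (chromosome 1, 182954788 to 182976044, plus strand, GRCm38/mm10), was higher in Pyy-labelled colonic cells, at 7.13 ± 4.43 CPM (SD, n = 6; 16 to 206 counts per library) against 0.550 ± 0.492 CPM (SD, n = 8) in unlabelled cells. Its log2 fold change was 2.94 (SE 0.44, edgeR adjusted p = 4.04e-05). The lowest labelled library, at 2.42 CPM, lay above the highest unlabelled library, at 1.49 CPM (two-sided exact permutation p = 0.000666, the smallest the design allows, 0.00799 adjusted over 24 toll-like receptor tests). The difference of the means was 6.58 CPM, and 4.25 CPM with TMM-scaled CPM (exact permutation p = 0.000666). In the small intestine Tlr5 stood at 1.51 ± 1.60 CPM (SD, n = 5) in labelled and 0.277 ± 0.362 CPM (SD, n = 5) in unlabelled cells, under the low-count filter. The exact permutation p was 0.0873 (adjusted 0.233), or 0.0318 unadjusted without the labelled library of Cck mouse 3. Without the labelled library of Cck mouse 4 the difference of the means fell from 1.23 to 0.584 CPM (exact permutation p = 0.175). That test ignores the pairing by animal. Tlr5 was higher in the labelled library of 5 of 5 same-animal pairs in each segment. In the small intestine the pairs of Cck mice 1 to 5 held 9 against 1, 3 against 1, 1 against 0, 84 against 5 and 15 against 2 counts. Some of these are at or under the floor of 3 counts. The exact sign-flip permutation p was 0.0625 in each segment, the smallest that 5 pairs allow, a test chosen after the data were seen. This comparison of segments was chosen after the values were seen: the label effects on Tlr5 were not shown to differ (colon minus small intestine 0.83, SE 1.16, edgeR adjusted p = 0.739; -0.14 without the unlabelled small intestinal library of Cck mouse 4, 0.18 without the labelled colonic library of Pyy mouse 9).

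Other toll-like receptors were mostly near the detection limit. In the small intestine Tlr3, a double-stranded RNA receptor, was lower in labelled cells (4.95 ± 2.32 against 14.1 ± 11.2 CPM, SD, n = 5 each; -1.87, SE 0.52, edgeR adjusted p = 0.014), though not by the exact permutation test (p = 0.0714, adjusted 0.214). It missed the threshold without the unlabelled library of Cck mouse 4 (-1.29, adjusted p = 0.0561). Tlr2, a lipoprotein receptor, stood at 6.29 ± 2.80 against 1.44 ± 1.21 CPM (1.73, SE 0.71, adjusted p = 0.0801); it passed without the unlabelled library of Cck mouse 1 (2.21, adjusted p = 0.0404) and in DESeq2 (adjusted p = 0.0328), and its exact permutation p was 0.0159 (adjusted 0.0952). In the colon Tlr1 was lower at the edge of the threshold (1.76 ± 2.12, n = 6, against 3.45 ± 2.95 CPM, n = 8, SD; -1.52, SE 0.61, edgeR adjusted p = 0.0468), and did not pass the exact permutation test (p = 0.26, adjusted 0.417). The call was lost when any of 9 libraries was left out, and the value was -2.36 without the labelled library of Pyy mouse 9. Colonic Tlr4, the lipopolysaccharide receptor, stood at 1.53 ± 0.84 (n = 6) against 0.451 ± 0.615 CPM (n = 8; SD; 1.14, SE 0.53, edgeR adjusted p = 0.0847; exact permutation p = 0.0233, adjusted 0.112). Colonic Tlr2 stood at 0.73 (adjusted p = 0.126; exact permutation p = 0.00932, adjusted 0.0746) and Tlr3 at -0.56 (adjusted p = 0.178). The toll-like receptor list as a whole did not pass in the colon (camera adjusted p = 0.648), and with 2 members tested it was given no list test in the small intestine. Tlr12 averaged 0.671 in labelled and 0.0577 CPM in unlabelled colonic libraries (exact permutation p = 0.000666, adjusted 0.00799). It was under the low-count filter there, so edgeR gave no test, and the permutation test used CPM without TMM scaling. The unlabelled mean lay below a count of 3 in every unlabelled colonic library, which is at least 0.0719 CPM. Mean levels of Tlr6, Tlr7, Tlr8, Tlr9, Tlr11 and Tlr13 were at most 1.13 CPM in every epithelial population, that of small intestinal unlabelled Tlr6. In nodose libraries Tlr2 averaged 3.58 CPM and Tlr3 2.47 CPM, Tlr5 was at 5.29 CPM in the library of Cck mouse 2 and at most 0.182 CPM in the other 4, and the rest averaged at most 0.913 CPM. In dorsal root libraries Tlr3 averaged 1.15 CPM, Tlr2 1.12 CPM, Tlr5 0.385 ± 0.389 CPM (SD, n = 12) and the rest at most 0.355 CPM.

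**Figure D3:**
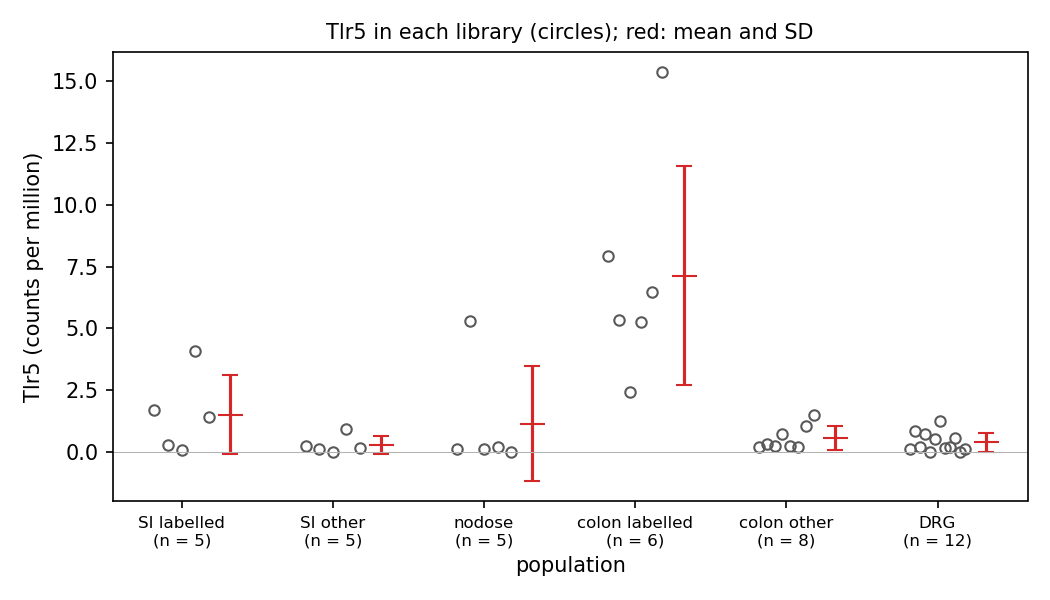
Tlr5 (CPM, y axis) in each library (circles) of the 6 populations (x axis; SI, small intestine; other, unlabelled epithelium; DRG, dorsal root ganglion), with the mean and SD in red. The 6 labelled colonic libraries, from 2.42 to 15.4 CPM, lie above all 8 unlabelled colonic libraries, whose highest is 1.49 CPM.

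The label effects of the 2 gut segments were then set against each other. Segment and reporter line changed together, so which cells each reporter marks cannot be told apart from the segment in these differences. Tph1 rose in labelled small intestinal cells and not in labelled colonic cells, a difference of -7.70 (SE 0.65, edgeR adjusted p = 2.22e-08), and Tac1 differed by -5.88 (SE 0.38, adjusted p = 8.75e-11). Both, with Lmx1a (-6.80, SE 0.72), a transcription factor of enterochromaffin cells, and Pou2f3, a tuft cell transcription factor (-7.27, SE 1.44; -9.07 without the unlabelled library of Cck mouse 1, -8.00 without the labelled library of Pyy mouse 9), were singled out after their values were seen. Pou2f3 was under the low-count filter in both segments when each was tested alone, and Lmx1a in the colon. Chga (-3.36, SE 0.50), Chgb (-4.44, SE 0.56), Ffar2 (-3.36, SE 0.45) and Trpa1 (-5.02, SE 0.62) also had smaller label effects in the colon. Afp (alpha-fetoprotein) differed by -8.41 (SE 0.78, adjusted p = 8.08e-08), with 127992 counts over the labelled small intestinal libraries and 15 over the labelled colonic ones. Of 18271 genes tested, 813 had a higher and 626 a lower label effect in the colon, so 56.5% of calls were higher. With DESeq2 size factors 44.8% of 1366 calls were higher and 754 were lower.

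Among the lists, tuft genes had lower label effects in the colon in 11 of 14 members (camera adjusted p = 1.07e-13; adjusted p = 0.0229 with an estimated correlation). Members included Sh2d6 (-6.95, SE 0.89) and Dclk1 (-4.27, SE 0.60). Gut region genes had higher label effects in 4 of 17 (camera adjusted p = 0.000463; adjusted p = 0.0229 with an estimated correlation). Members included Hoxb8 (4.05, SE 0.54) and Pdx1 (3.06, SE 0.62). Goblet genes were higher in 6 and lower in 1 of 14 (camera adjusted p = 0.018; adjusted p = 0.75 with an estimated correlation). Members included Clca1 at 5.30 (SE 0.91), Zg16 at 4.53 (SE 0.90) and Muc2 at 3.54 (SE 0.61). Enterocyte genes were higher in 4 of 21, among them Slc15a1 (2.73, SE 0.51; camera adjusted p = 8.37e-05, adjusted p = 0.75 with an estimated correlation), and pan-neuronal genes in 5 of 18, among them Map2 (4.04, SE 0.77; 0.00837, and 0.75 with an estimated correlation). Stem and cycling genes were lower in 3 of 16, among them Smoc2 (-1.67, SE 0.39; 7.69e-05, and 0.401 with an estimated correlation), and immune genes in 2 of 19, Ptprc (-3.48, SE 0.99) and C1qa (-4.94, SE 0.90; 0.018, and 0.75 with an estimated correlation). The largest single difference among called genes, that of Pdcd1 (-9.87, SE 1.55), was sparse, though that of Afp above was not. Pdcd1 had 87 counts over labelled small intestinal libraries and no count in labelled colonic ones. Its fitted value is therefore not a bound on the fold. It was -12.46 without the unlabelled library of Cck mouse 4 and -9.24 in the DESeq2 Wald test. Adjusted over the list alone, the calls were 12 lower tuft, 6 higher gut region, 7 higher goblet, 6 higher pan-neuronal, 9 lower stem and cycling, and 1 higher and 8 lower immune genes. Without the labelled colonic library of Pyy mouse 9, the counts were 380 higher and 1109 lower. Among 12468 genes tested in both segments, 1360 were higher in both (485.4 expected of independent lists), 1300 lower in both (473.2 expected), and 117 went opposite ways. The fold changes correlated across genes, which are not independent replicates, with a Pearson r of 0.68 and a Spearman rho of 0.65.

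Nodose libraries were compared with the small intestinal epithelium of the same line, as a check on the neurons and for their receptors of gut signals. Cckar, the cholecystokinin receptor, stood at 207.2 ± 34.5 CPM (SD, n = 5; log2 fold change 6.47, SE 0.36, edgeR adjusted p = 3.92e-11) and the serotonin-gated channel Htr3a at 874.4 ± 226.1 CPM (6.58, SE 0.32). Glp1r stood at 53.5 ± 14.2 CPM and the peptide YY receptor Npy2r at 42.5 ± 10.2 CPM. Of 15428 genes tested, 4913 were higher and 4442 lower in nodose libraries. All 18 pan-neuronal genes were higher (camera adjusted p = 2.61e-10; adjusted p = 0.118 with an estimated correlation), including Uchl1 (5.77, SE 0.30) and Prph (6.08, SE 0.37). Nodose genes were higher in 13 and lower in 1 of 14 (1.22e-06; 0.118 with an estimated correlation), including the ATP receptor P2rx2 (6.03, SE 0.26). Dorsal root genes were higher in 17 and lower in 1 of 19 (5.38e-07; 0.118 with an estimated correlation), including the heat-gated channel Trpv1 (6.15, SE 0.33) and Hoxb5 (6.42, SE 0.36). Vesicle release genes were higher in 28 and lower in 5 of 35 (5.38e-07; 0.133 with an estimated correlation), including the glutamate transporter Slc17a6 (6.46, SE 0.45). Ion channel genes were higher in 22 and lower in 1 of 27 (9.77e-06; 0.133 with an estimated correlation), including the sodium channel Scn10a (5.78, SE 0.39), and gut signal receptors in 14 and 2 lower of 20 (6.21e-05; 0.118 with an estimated correlation), including the glutamate receptor Gria4 (6.70, SE 0.37). Glial genes were higher in 13 of 14 and stromal genes in 12 of 12, so the ganglion libraries also held transcripts of non-neuronal cells. Adjusted over the list alone, vesicle genes had 29 higher and ion channel genes 2 lower. The largest separated increases were Ednra (7.93, SE 0.59), the potassium channel Kcnk18 (7.35, SE 0.58), Cavin2 (7.25, SE 0.47), Defb42 (7.24, SE 0.53) and Ucn2 (7.59, SE 0.90; 5.75 without the nodose library of Cck mouse 5). The largest decreases were the histone gene Hist1h1b (-9.36, SE 0.48; -10.23 without the nodose library of Cck mouse 4) and the epithelial genes Eps8l3 (-8.42, SE 0.37), B4galnt2 (-8.33, SE 0.43), Fermt1 (-8.12, SE 0.41) and Clca3b (-7.95, SE 0.42).

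Dorsal root libraries were compared with colonic epithelium for the same purpose. Calca (6.61, SE 0.16) and Calcb (7.18, SE 0.24), the calcitonin gene-related peptides of nociceptors, and the neurofilaments Nefl (6.66, SE 0.19) and Nefh (7.22, SE 0.22) were higher in the 12 dorsal root libraries, with edgeR adjusted p values of at most 2.32e-21. Of 18741 genes tested, 7187 were higher and 6919 lower, a balance that turned to 6624 higher and 7637 lower with DESeq2 size factors. All 18 pan-neuronal genes were higher (camera adjusted p = 1.68e-12; adjusted p = 0.0513 with an estimated correlation), as were 25 of 27 dorsal root genes (1.03e-11; 0.00665 with an estimated correlation). Also higher were 32 of 36 vesicle release genes with 3 lower (1.62e-08; 0.0513 with an estimated correlation), among them Snap25 (4.90, SE 0.14), and 20 of 28 ion channel genes with 2 lower (0.000503; 0.163 with an estimated correlation), among them Scn10a (5.76, SE 0.25) and the touch channel Piezo2 (4.84, SE 0.23). Gut signal receptors were higher in 17 and lower in 4 of 25 (0.00274; 0.148 with an estimated correlation), including the kainate receptor Grik1 (6.40, SE 0.27) and the ATP receptor P2rx3 (5.26, SE 0.28). Nodose genes were higher in 8 and lower in 3 of 11 (0.0269; 0.194 with an estimated correlation), including Htr3a (4.53, SE 0.21) and Calb1 (5.90, SE 0.17). Glial genes were higher in 13 of 14, stromal genes in 15 of 16 and blood genes in 5 of 5, Hbb-bt among them at 7.61 (SE 0.47), a globin that shares 3′ sequence with its copies. The other largest increases were Map7d2 (7.77, SE 0.31; 6.05 in the DESeq2 Wald test), Trappc3l (7.63, SE 0.35), Camp, a neutrophil granule peptide (8.45, SE 0.65; 7.76 without Pyy mouse 12), and Ptgds (7.93, SE 0.76; 6.92 without Pyy mouse 7). The largest decreases were Eps8l3 (-8.30, SE 0.28), Ang5 (-8.05, SE 0.75), Ang4 (-8.02, SE 0.71), the sulfotransferase Sult1d1 (-7.69, SE 0.22) and Clca1 (-7.67, SE 0.58).

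Dorsal root and nodose libraries were finally compared directly, as a description, since ganglion, reporter line and library pool changed together and cannot be told apart. Cckar stood at 4.07 ± 1.36 CPM in dorsal root (SD, n = 12) against 207.2 ± 34.5 CPM in nodose libraries (SD, n = 5), a log2 fold change of -4.95 (SE 0.17, edgeR adjusted p = 3.79e-17). Glp1r stood at 0.236 ± 0.191 against 53.5 ± 14.2 CPM (-6.90, SE 0.32). Htr3a stood at 67.2 ± 13.8 against 874.4 ± 226.1 CPM, with P2rx2 at -5.47 (SE 0.23). The positional gene Hoxa7 was higher in dorsal root libraries (8.11, SE 0.34; 8.89 without the nodose library of Cck mouse 2) and Hoxb5 lower (-4.51, SE 0.22), and Pvalb (5.98, SE 0.32), Nefh (2.97, SE 0.16) and Piezo2 (2.67, SE 0.31) were higher. Of 16486 genes, 5067 were higher and 4215 lower in dorsal root libraries. Nodose genes were lower in 10 and higher in 4 of 14 (camera adjusted p = 0.00106; adjusted p = 0.298 with an estimated correlation). Gut signal receptors were lower in 12 and higher in 5 of 24 (0.0138; adjusted p = 0.301 with an estimated correlation) and vesicle release genes lower in 19 and higher in 6 of 36 (0.0138; adjusted p = 0.406 with an estimated correlation). Vesicle genes included Syt4 (-2.34, SE 0.14), and 7 were higher when adjusted over the list alone. Dorsal root genes were higher in 15 and lower in 6 of 26 (0.239), ion channel genes higher in 4 and lower in 11 of 28 (0.102), among them Scn3a (-2.82, SE 0.30), and pan-neuronal genes higher in 6 and lower in 11 of 18 (0.105; median -0.46, mean 0.05). Other nodose-high genes were the peptide Uts2b (-9.02, SE 0.34), Myl1 (-8.64, SE 0.39), Fabp1 (-8.10, SE 0.37; -8.70 without the library of Pyy mouse 1) and Efcab6 (-7.11, SE 0.22). Fabp1 stood at 78.5 CPM in nodose libraries and at 10280 CPM in the unlabelled small intestinal libraries of the same pool, and enterocyte genes as a list were lower in 11 and higher in 2 of 15 (median -2.01). The largest dorsal root increases, mt-Atp6 (17.86, SE 0.58), mt-Co2 (16.97, SE 0.53), mt-Co3 (16.95, SE 0.48), mt-Nd3 (14.27, SE 0.46) and Hba-a2 (14.90, SE 0.67), were all genes with a near-identical transcript copy. At most 22 counts of any of them were seen over the 5 nodose libraries, and mt-Atp6 stood at 20.11 without that of Cck mouse 5 and mt-Nd3 at 15.06 without that of Cck mouse 4. Leaving out every gene with such a copy gave 3151 higher and 2803 lower. Those 5 values therefore compare the counting of the 2 tables as well as the ganglia. Blood genes as a list summed to a mean of 29760 CPM in dorsal root and 547.8 CPM in nodose libraries. The list includes Hba-a2, so that difference may hold the same effect of counting.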

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

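The tests of the tuft pattern, and the choice of the genes Tph1, Tac1, Lmx1a and Pou2f3, were made only after the result was seen. In 10 of 49 groups of libraries, 1 library lay far from the others of its population by Dixon's test. Chance gives that in about 1 of 20 groups of normal, independent values. CPM near the floor are not such values, and several flags share a library, so the 10 groups do not measure an excess over chance. Among unlabelled small intestinal libraries, that of Cck mouse 4 stood apart for Cck (184.3 CPM), Pyy (148.1 CPM) and Tlr5 (0.91 CPM). Among unlabelled colonic libraries, that of Pyy mouse 2 stood apart for Pyy (1772 CPM), Gcg (441.1 CPM), Insl5 (105.3 CPM) and Cck (20.2 CPM), all of them hormones of the labelled cells. The unlabelled colonic library of Pyy mouse 11 stood apart for Tlr4 (1.94 CPM), the labelled colonic library of Pyy mouse 9 for Tlr1 (5.75 CPM) and the nodose library of Cck mouse 2 for Tlr5 (5.29 CPM).

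The label effect differed between the segments for 40 of the genes named, by a test of the difference itself (colon minus small intestine, log2, edgeR adjusted p of at most 0.0489). Segment and reporter line cannot be told apart in these differences. Endocrine and sensory genes with a lower label effect in the colon were Tph1 (-7.70), Lmx1a (-6.80), Tac1 (-5.88), Trpa1 (-5.02), Chgb (-4.44), Stxbp5l (-4.02), Ffar2 (-3.36), Chga (-3.36) and Sstr1 (-2.76). Tuft and immune genes with a lower one were Pou2f3 (-7.27), Sh2d6 (-6.95), C1qa (-4.94), Rac2 (-4.71), Dclk1 (-4.27) and Ptprc (-3.48). Of other genes the effect was lower for Cyp2f2 (-8.76), Afp (-8.41), Fmo2 (-6.76), Krt19 (-2.08) and Smoc2 (-1.67). Goblet and other genes lower with the label in the small intestine had a higher label effect in the colon, namely Fer1l6 (5.31), Clca1 (5.30), Zg16 (4.53), Muc2 (3.54), Bcas1 (3.13) and Lrrc26 (2.35). It was also higher for Hoxb8 (4.05), Map2 (4.04), Slc10a5 (3.85), Pdx1 (3.06), Slc15a1 (2.73), Nlrc4 (1.69) and Ifih1 (1.60). Of these genes, Pou2f3 was under the low-count filter in both segments when each was tested alone. Lmx1a, Trpa1, Sstr1, C1qa, Afp, Fmo2 and Pdx1 were under it in the colon, and Hoxb8 in the small intestine. The sparse genes Sval1 (7.46), Tmem89 (7.24), A430106G13Rik (7.87) and Ms4a5 (7.44) had higher and Pdcd1 (-9.87), AC132288.1 (-9.72) and Gm10384 (-8.52) lower fitted differences. Fitted values of genes without a count in a population depend on the prior count and are no bound. Single libraries left out moved Sval1 to between 6.80 and 8.04, Tmem89 to between 6.49 and 8.49, A430106G13Rik to between 6.61 and 8.94, Gm10384 to between -9.32 and -6.05 and Cyp2f2 to -9.52. AC132288.1 stood at -10.43 without the labelled library of Pyy mouse 4. In the DESeq2 Wald test Gm10384 stood at -7.54 and AC132288.1 at -8.85. Ms4a5 stood at 3.58 without the unlabelled small intestinal library of Cck mouse 2 (adjusted p = 0.947).

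Tuft markers rose with the label in the small intestine and had a median difference of -5.46 between the segments. A lower share of absorptive cells among labelled small intestinal cells would raise goblet genes as well. Their median label effect there was -2.52, but sorting for an endocrine reporter would lower goblet genes whatever the absorptive share, so this cannot decide. Immune transcripts in unlabelled colonic libraries would leave tuft genes not commonly expressed by immune cells alike, but 6 of 8 such genes had a lower label effect in the colon, with a median of -5.47. Different counting of near-identical copies is argued against by 0 of 14 tested tuft members having a 3′ copy. A difference between the segments, or between the reporters, in which cells carry the label was not tested and stays open.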

How the results depend on the processing

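Alternatives without the unlabelled colonic libraries of Pyy mice 3 and 5, without alpha-defensin genes, with sex as a covariate, without the unlabelled library of Cck mouse 4 as a doubted library, and without genes that have a 3′ copy were chosen only after the data were seen, as was the share that defines a copy. Over 183 gene-level results, 3588 values under an alternative kept their direction and side of the threshold, 70 kept direction but missed the threshold, 2 newly passed it and 1 reversed. The 2 are those of Tlr2 in the small intestine, and the reversed 1 is the Tlr5 difference between segments, which ran from -0.14 to 1.73 over libraries left out. Most of the 70 belonged to Nmb (17), Tlr1 (13), Stmn2 (12), S100b (8) and Pdx1 (8).

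Against a 2-fold change, glmTreat called 1037 higher and 448 lower genes in the small intestine and 1222 and 595 in the colon, a stricter test by construction. Leaving out each library gave 1809 to 2466 higher and 1690 to 1951 lower in the small intestine, and 3473 to 3949 and 3786 to 4127 in the colon. With the replicate block (animal) the counts were 2170 higher and 1895 lower in the small intestine and 3181 and 3513 in the colon. The block ended the calls of Stmn2, S100b and Pdx1 and changed those of the lists named in the report, and it changed no other edgeR or list call named between labelled and unlabelled cells, the only comparisons it was run in. Without a low-count filter 61.1% of small intestinal calls were higher, against 50.7%.

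For the difference of label effects, the DESeq2 Wald test gave 920 higher and 1062 lower genes and no low-count filter gave 395 higher of 1028 called (38.4%). Leaving out a library gave 380 to 1012 higher and 514 to 1109 lower, with 380 and 1109 without the labelled colonic library of Pyy mouse 9, so the balance of directions changed with the filter and that library, as it did with DESeq2 size factors (44.8% higher), which the Wald test also uses. Without the unlabelled colonic libraries of Pyy mice 3 and 5 68.1% of calls were higher. Between ganglia, no low-count filter gave 7639 higher genes, and leaving out genes with a 3′ copy gave 3151 higher and 2803 lower. Except for the smaller set of genes in the last, the cause was not tested.

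With an estimated correlation, the camera lists past the threshold went from 14 to 2 in the small intestine, 11 to 0 in the colon (4 unadjusted, fry 15), 6 to 0 for nodose (1 unadjusted, fry 6), 6 to 1 for dorsal root against epithelium, 7 to 2 for the comparison of segments (fry 3) and 3 to 0 between ganglia (1 unadjusted, fry 4). The Tlr5 difference in the small intestine ran from 0.584 to 1.59 CPM over libraries left out, the lowest without the labelled library of Cck mouse 4 and the highest without that of Cck mouse 3, where it passed an unadjusted exact permutation test. In the colon it ran from 4.93, without the labelled library of Pyy mouse 9, to 7.52 CPM. In TMM-scaled CPM the colonic difference was 4.25 against 6.58 CPM. Over the 5 same-animal pairs, a replicate block test chosen after the data were seen, the Tlr5 difference was 4.97 CPM in the colon and 1.23 CPM in the small intestine (exact sign-flip permutation p = 0.0625 in each, the smallest 5 pairs allow), so this test could not pass at 0.05 in either segment; the edgeR call of colonic Tlr5 held in 25 of 25 alternatives. A count of 3 is up to 0.664 CPM in small intestinal libraries.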

Other observations

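The ileal ratio test and the splits for the colon, the comparison of segments and the ganglia were written before their results were seen. The other tests here were chosen only after. They cover defensin copies, proximal epithelium, the ileal rank correlation, barcode exchange and carry-over of unlabelled epithelium. The splits for the small intestine, nodose and dorsal root comparisons were also chosen only after. Paneth transcripts were abundant in unlabelled colonic libraries. Shared reads between near-identical defensins are argued against, since the 4 Paneth genes without a copy had a median label effect of -4.31 and 3 of them were called lower. Without the unlabelled libraries of Pyy mice 3 and 5 the effect was smaller, at -3.07 for Mmp7 and -2.69 for Itln1. Epithelium of the proximal small intestine, in the proportions of the unlabelled libraries there, is argued against as the whole source in 7 of 8 libraries, where enterocyte over Paneth fractions of that level were 0.0513 to 0.268; a smaller share stays open. In the library of Pyy mouse 11, which had the lowest Paneth fraction, the ratio was 1.76, and in that 1 library this source cannot be told apart from others. Of the 4 genes Pla2g2a stood at no more than 0.341% of the small intestinal level in any of the 8 libraries, against 8.62 to 88.3% for the other 3, and a strain variant was not tested. Carry-over of ileal epithelium cannot be told apart from other sources. Fabp6 and Slc10a2 summed stood at 2.45 to 41.4 times the level of Mmp7. That met the outcome set beforehand for this source, a sum of at least the Mmp7 level in most of the 8 libraries. Nearly all of the sum was Fabp6, however, and Slc10a2 alone lay below Mmp7 in 8 of 8 libraries. The sum was also lowest in the library with the highest Paneth fraction and highest in the one with the lowest (Spearman rho -0.52 over the 8). The usual colonic level of Fabp6 was not measured here, and Paneth-like cells of the colon itself were not tested.

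Neuron libraries held low levels of epithelial transcripts. Exchange of barcodes within a sequencing pool would bring hormones and other epithelial genes in the proportion of the pool, and the ratio of their fractions was 1.13 in nodose (1.01 to 1.22) and 0.756 in dorsal root libraries (0.565 to 0.986). Carry-over of epithelium like the unlabelled libraries would bring them in the proportion seen there. The ratio was at least 85.8 times that proportion in nodose and 34.1 times in dorsal root libraries. Unsorted epithelium also holds the labelled cells, in a share not measured here, so its carry-over was not tested. Exchange is therefore a candidate explanation, at a median of 2.38% of the pool level of hormones in nodose and 1.41% in dorsal root libraries. Low levels of any transcript abundant elsewhere in a pool, in epithelial libraries too, may hold such a share.

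Whether chance could give such counts was examined by repeating each test on other splits, where 1 split, the real one, gave as many genes in each comparison. In the small intestine the real split called 4102 genes and the highest of the others 1, of 100 splits. The figures were 7884 and 2187 of 100 in the colon, 9355 and 2756 of 100 for nodose against epithelium, and 14106 and 3042 of 60 for dorsal root against epithelium. They were 1439 and 78 of 60 for the comparison of segments, and 9282 and 1809 of 100 between ganglia. These counts thus depend on the real grouping. Other splits mix populations sorted or dissected as different cells, which widens the spread, so few calls were likely from them in advance. Whether chance could give the counts is therefore not decided by this test. The real split parts 5 same-animal pairs in each segment, and the 13 and 5 other splits that part as many called no gene in edgeR.

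Mitochondrial transcripts took 12.5 ± 1.62% of counts in labelled and 21.1 ± 1.51% in unlabelled small intestinal libraries (SD, n = 5 each; two-sided exact permutation p = 0.00794, 0.0119 adjusted over 6 library measures). In the colon they took 7.48 ± 1.86% (SD, n = 6) and 7.09 ± 4.50% (SD, n = 8), with an exact permutation p of 0.84. Both tests ignored the pairing of libraries by animal. Several mitochondrial transcripts are almost absent from the Cck table alone, so the shares are not comparable between segments. Colonic shares also depend on defensin counts, which are in the same total. The unlabelled library of Pyy mouse 3 held 1.64% mitochondrial and 73.2% defensin counts, and that of Pyy mouse 11 held 15.65% and 6.47%.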
